A study of Mus musculus with 3 samples.

How the data were processed

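Total RNA from cultured aortic endothelial cells of Pim1 knockout and wild-type mice had been amplified, labelled and hybridised to 3 two-colour 60-mer oligonucleotide arrays, with the knockout in Cy5 (red) and the wild type in Cy3 (green), per the labels. The deposited files held, for each of 45018 spots per array, mean and median pixel intensity and local background intensity in both channels, written by Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes. They also held the software's own processed intensities, which were background-subtracted and dye-normalised, and its log10 ratio of red over green, per the file headers. The deposited value table held a log10 ratio that was identical to the software's (largest difference 0 on each array, median 0), so its scale and direction were known. The software's log10 ratio lay within 0.001 of the log10 ratio of the deposited processed intensities at 75.5%, 75.1% and 71.1% of spots and differed by at most 0.205; where and why they differed was not settled. All 3 arrays came from 1 slide and 1 scan date, so neither could act as a batch.

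From the mean pixel intensities and median local backgrounds, background was corrected with normexp (offset 50) and log2 ratios were normalised within each array by loess, in which 1639 control spots and outlier-flagged spots had weight 0. No scaling between arrays was applied. Outlier-flagged spots (121, 140 and 136 on the 3 arrays) were left out and spots of 1 probe were averaged, which gave 41174 probes. No spot was saturated. A probe was tested where it lay well above background in 1 channel on at least 2 of the 3 arrays. The offset pulls ratios of dim probes towards 0. A probe not well above background in 1 channel on every array was given as a bound, from channel values after loess and Aquantile normalisation.

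Probes were named through RefSeq accessions of the GRCm38 annotation, used for names only. Of the probes, 24375 matched by accession, 115 by another accession listed for the probe, 6234 by symbol and 2391 by synonym, 8059 had no name, and 19757 genes were named. Coordinates are those of the array files (mm8). The 217 probes against the strand of their gene were left out of gene values. A gene was represented by its brightest tested probe. Where a second probe of another, possibly overlapping, sequence existed for a gene changed at least 2-fold (381 genes), its ratio had the same sign in 373.

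The mean log2 ratio of the 3 arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 3.46), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Errors given with ± are SDs over 3 arrays. Of the lists fixed before the data were examined, 34 in all, 32 were tested with camera at a preset correlation of 0.01, with adjustment over the lists. The estimated-correlation form of camera and fry, which tests whether genes of a list change on balance 1 way or, in its mixed form, in either direction, were alternatives. The Pim kinases and the sex-linked genes were given as single values. Genes were named by a rule set beforehand: Pim1, Pim2 and Pim3, the 12 largest rises and 12 largest falls among called genes with the same sign on all arrays (unnamed clones skipped), and up to 4 called members of each list by size of change. That rule took 143 genes, some of which are not reported here. List members Hspg2, Ccl21a, Bcl2a1a, Lif, Xaf1, H2-L, H2-Q4, H2-M2 and Rn18s were not analysed here.

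The pipeline was tested on simulated intensities with 25080 probes, of which 50 were changed by each of 4 fold sizes. Of 50 probes changed 1.5-fold, 3 were called in the right direction, of 50 changed 2-fold 21, of 50 changed 4-fold 43 and of 50 changed 8-fold 48. The median measured fold of the 8-fold probes was 6.80. Of 121 calls, 5 were unchanged probes (4.13%). In the same simulation, with 13490 genes, a list of 40 genes shifted by 0.5 passed camera with the preset correlation (adjusted p = 8.515e-27) and none of 20 unshifted lists did. The simulation made 121 calls against 4300 in the data, so its cut-off on the unadjusted p was stricter. The detection rates above therefore need not hold for the data. The simulation did not include the difference of array 1 from the others. Its probes varied independently of each other, so it did not test the preset correlation on lists with correlated genes.

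Alternatives fixed beforehand were no background subtraction, an offset of 0, median pixel intensities, the software's log ratio, the deposited value table, median centring, scaling or Aquantile between arrays, no filter or a filter on both channels, flagged spots kept, an intensity trend with robust variances, array weights, a separate-channel fit (with statmod 1.5.0), an adjusted p under 0.01, a test against a log2 ratio of 0.5, the mean of a gene's probes, and leaving out each replicate. Counts without chromosomes X and Y, and the Pim1 window without MHC genes, were added after seeing the data. For lists, the adjusted p and not the median was compared between alternatives, a choice made after the first results because other set tests leave the median unchanged.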

Results

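Gene expression was compared between cultured cells of mice that lack the serine/threonine kinase Pim1 and those of wild-type mice, both of the FVB/N strain. The labels called the cells aortic endothelial cells, and their identity rests on the labels alone. The labels described the donors as female and 12 weeks old, and RNA was prepared 24 hours after the cells were seeded. It was hybridised to 3 two-colour arrays. Each array carried knockout RNA labelled with Cy5 and wild-type RNA labelled with Cy3, and the labels called the 3 arrays biological replicates. All ratios are knockout over wild type. No dyes were swapped, so dye effects were not balanced between the genotypes. The labels did not say whether the wild-type RNA came from 1 pool or from separate cultures, and p-values measure only the spread between these 3 arrays, whose number limits the precision. Between 53.9% and 57.2% of the probes lay well above background in the knockout channel and between 58.4% and 62.6% in the wild-type channel. Across probes, which are not independent replicates, log2 ratios correlated at r = 0.905 between arrays 2 and 3 and at r = 0.681 and 0.699 between array 1 and the others.

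The targeted gene was measured first. The sense probe for Pim1, at 29220807 to 29220866 on chromosome 17 in the coordinates of the array files (mm8), fell by 1.04 on the log2 scale (SD 0.10, n = 3 arrays, limma adjusted p = 0.00297). It read −0.97, −1.16 and −0.99 on the 3 arrays and lay well above background in both channels on each. The labels did not say which part of the gene was removed, and a probe outside that part checks nothing. The paralogs Pim2 (log2 ratio −0.21 ± 0.06, adjusted p = 0.19) and Pim3 (−0.27 ± 0.39, adjusted p = 0.331) did not pass the threshold, although Pim3 did without replicate 1 (adjusted p = 0.00184).

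Genes of the sex chromosomes differed between the channels, although both were labelled female. An effect of sex on the ratios of other genes therefore cannot be separated from the genotype in what follows. Xist, the RNA that coats the inactive X chromosome of female cells, was not well above background in the knockout channel on any array and was at least 168-fold lower there than in the wild-type channel (adjusted p = 0.000129). The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were not well above background in the wild-type channel on any array. They were at least 28.1-fold, 12.1-fold and 4.68-fold higher in the knockout channel (adjusted p = 0.000314, 0.000618 and 0.00105). Uty, also Y-linked, was not well above background in the wild-type channel on any array and was above it in the knockout channel on 2 of 3; its bound was at least 1.24-fold and it did not pass (adjusted p = 0.0719). Bounds of this kind are computed from channel values and are open to dye bias.

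Of 36 general endothelial markers on the array, 11 were well above background on all 3 arrays in the knockout channel and 14 in the wild-type channel, and 14 were above it on no array in either channel. Pecam1, Cdh5, Tie1 and Erg, singled out after their values were seen, were among those 14. Of the 15 markers tested, 2 rose and 3 fell, and 2 and 4 did so when adjusted over the list alone. Eng, a co-receptor for TGF-beta ligands, rose 5.68-fold (log2 ratio 2.51 ± 0.24), and Egfl7, a secreted endothelial factor, rose 2.67-fold. Fli1, an ETS transcription factor, fell by 0.87 on the log2 scale. The list did not pass (limma camera, adjusted p = 0.363), and its median (−0.17) and mean (0.00071) differed in sign. Among 15 arterial markers 4 fell and none rose, also over the list alone, led by the Notch ligand Jag2 (−1.54 ± 0.22), with adjusted p = 0.111 for the list. Of 6 venous and lymphatic markers 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.138 for the list). The lymphatic glycoprotein Pdpn rose 3.38-fold and the venous transcription factor Nr2f2 rose 1.61-fold. Calls were lost without replicate 2 or without replicate 3 for Fli1 (adjusted p = 0.0951 and 0.0507) and Nr2f2 (0.0609 and 0.154). Jag2 read −2.42 with the scanner software's log ratio.

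Knockout and wild-type cultures differed at many genes. Of 13490 genes tested, 2714 (20.1%) were called (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 1169 were higher and 1545 lower in the knockout. At least 2-fold changes were found for 901 genes, 304 higher and 597 lower, and at least 4-fold changes for 235, 72 higher and 163 lower. At the probe level 4300 of 25080 were called, 1911 higher and 2389 lower. The same direction held on all 3 arrays for 2710 of the 2714 called genes. The call rests on the same ratios and so favours this, and a gene without a value on all 3 arrays could not count. Xist and the Y-linked genes are part of these counts. Without chromosomes X and Y, a choice made after seeing the data, 2623 genes were called and 865 of them changed at least 2-fold. That does not remove an effect of sex on autosomal genes, which cannot be told apart from genotype here. The count of called genes was 5582 without replicate 1, 709 without replicate 2 and 616 without replicate 3, and the count of called probes was 9096, 970 and 843. The count of 2-fold genes was 1005, 667 and 612. Of the 901 genes changed at least 2-fold with all arrays, 798, 650 and 588 were among them. With median centring in place of loess, 1869 genes were called, of which 55.5% were higher in the knockout against 43.1% with loess. The log ratio of the scanner software gave 1701 genes changed at least 2-fold. With that ratio, 44 of 142 named genes had folds over 1.5 times larger and none had folds over 1.5 times smaller, and 30 did so with a normexp offset of 0. The offset used here pulls ratios of dim probes towards 0.

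The largest rises included Gdf10, Svep1 and Serpina3g. Gdf10, a ligand of the TGF-beta family, rose 32.01-fold (log2 ratio 5.0 ± 0.59, SD, n = 3 arrays), the matrix protein gene Svep1 rose 22.9-fold (4.52 ± 0.16) and the protease inhibitor Serpina3g rose 21.7-fold (4.44 ± 0.52). Thumpd1 (4.44 ± 0.29), the interleukin 36 receptor Il1rl2 (4.24 ± 0.25) and the T-box transcription factor Tbx1 (3.69 ± 0.07) followed. L3hypdh (3.59 ± 0.31), the secreted Wnt antagonist Frzb (3.55 ± 0.33) and the acute-phase gene Saa3 (3.49 ± 0.89) were also among the 12 largest rises, as were Eif2s3y and Ddx3y. Gdf10 (5.76), Thumpd1 (5.46) and Il1rl2 (5.32) read higher with the scanner software's log ratio.

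The largest falls reached further than the largest rises. Fhl1, a LIM domain protein, was 184-fold lower in the knockout (log2 ratio −7.52 ± 0.15) and stayed above background in both channels on all arrays. The collagen VI chain Col6a3 was 67.4-fold lower (−6.07 ± 0.31) and the Wnt modulator Sfrp2 was 29.4-fold lower (−4.88 ± 0.35). Ccdc68 (−4.80 ± 0.43), the LIM homeobox factor Lhx9 (−4.60 ± 0.14), the secreted factor Ndnf (−4.38 ± 0.25), the glutathione transferase Gsta1 (−4.22 ± 0.16), the protease inhibitor Serpine2 (−4.18 ± 0.13) and the sulfotransferase Chst7 (−4.14 ± 0.59) also fell. Xlr4b (−4.63 ± 0.28) was above background in the knockout channel on 2 of the 3 arrays. Xist was also among the 12 largest falls, and like Xist, the genes Fhl1, Xlr4b and Chst7 lie on chromosome X. Col6a3 (−7.25), Sfrp2 (−5.85), Ccdc68 (−6.02), Xlr4b (−6.49), Lhx9 (−6.45), Ndnf (−5.37), Gsta1 (−5.23), Serpine2 (−4.84) and Chst7 (−4.81) read lower with the scanner software's log ratio.

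**Figure D1:**
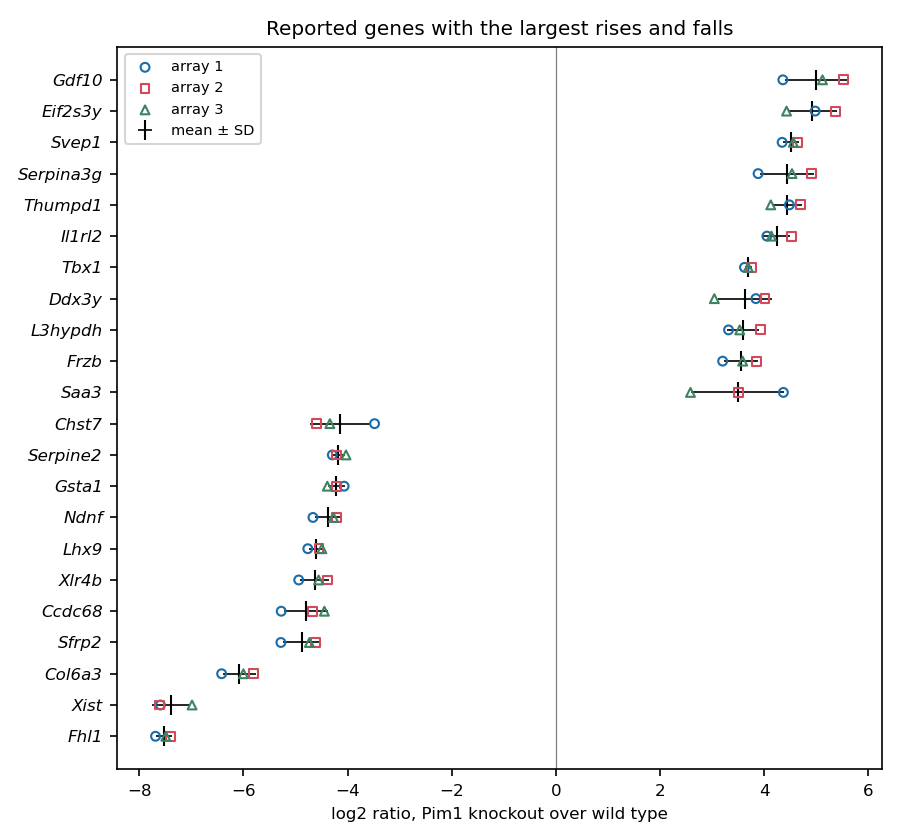
Log2 ratio of knockout over wild type (horizontal axis) on each array (symbols), with the mean and SD, for reported genes among the 12 largest rises and the 12 largest falls. The rises averaged from 3.49 for Saa3 to 5.0 for Gdf10 and the falls from −4.14 for Chst7 to −7.52 for Fhl1, and for Xist, Eif2s3y and Ddx3y 1 channel was at background.

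Gene lists were fixed before the data were examined, and 32 of them were tested as sets. With camera at a preset correlation of 0.01, 11 passed, 5 higher and 6 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.617. A simulated list of 40 genes shifted by 0.5 on the log2 scale also missed with an estimated correlation (adjusted p = 0.141). With 3 arrays that test thus missed a true shift of this size. Simulated genes varied independently, so the simulation does not show whether calls with the preset correlation hold for correlated genes. Estimated correlations in the 11 called lists ranged from −0.054 (smooth muscle and pericyte markers) to 0.637 (cholesterol synthesis).

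Among the adhesion lists, integrins, junctions and focal adhesion passed as lower with the preset correlation, and leukocyte adhesion molecules did not pass. Of 18 integrin genes tested, 9 fell and 1 rose (10 and 3 adjusted over the list alone), with a median log2 ratio of −0.42 (adjusted p = 0.0121). With an estimated correlation the adjusted p was 0.617, and with probes above background in both channels on all arrays it was 0.0729. Itgb4, the partner of Itga6 in the laminin receptor of hemidesmosomes, was 11.4-fold lower (−3.51 ± 0.36), Itga6 was 3.08-fold lower (−1.62 ± 0.50) and Itga3 was 2.67-fold lower. The collagen receptor subunit Itga11 rose 4.86-fold. Of 34 genes of cell-cell junctions, 13 fell and 2 rose (16 and 4 adjusted over the list alone), with a median of −0.22 (adjusted p = 0.0121, and adjusted p = 0.617 with an estimated correlation). The desmosomal genes Pkp1 (−3.41 ± 0.29) and Pkp2 (−2.16 ± 0.28) and the cadherin Cdh13 (−3.40 ± 0.24) fell, and Nectin2 rose 3.52-fold. Of 60 focal adhesion and actin genes, 21 fell and 4 rose, also over the list alone, with a median of −0.29 (adjusted p = 0.000331, and adjusted p = 0.617 with an estimated correlation). Among them the myosin light chain Myl9 (−2.11 ± 0.56) and Lims2 (−1.66 ± 0.15) fell and Zyx rose 2.82-fold. Mesothelial and epithelial markers (median −0.58) and smooth muscle markers (median −0.29) moved the same way, each with adjusted p = 0.617 with an estimated correlation. Of 18 leukocyte adhesion molecules, 4 rose and 5 fell (5 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.874). Icam1 (−2.31 ± 0.66), Mcam (−1.77 ± 0.17) and the selectin Selp (−1.59 ± 0.32) fell, whereas Vcam1 rose 3.88-fold. Without replicate 3, Itga6 lost its call (adjusted p = 0.0716). Itga11 read 2.96, Icam1 −3.13, Mcam −2.49 and Lims2 −2.36 with the scanner software's log ratio.

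Markers of some other cell types also shifted with the preset correlation, while the macrophage and adipocyte lists did not pass. On all arrays, 10 of 25 macrophage and leukocyte markers were well above background in the knockout channel and 13 in the wild-type channel. On no array in either channel were 7 of the 25 above it. For 13 adipocyte markers these counts were 5, 5 and 6. Of 26 fibroblast markers on the array, 23 were well above background on all arrays in the knockout channel and 22 in the wild-type channel, and 10 stand in another list too. Of 24 fibroblast markers, 13 rose and 2 fell (14 and 4 adjusted over the list alone), with a median of 0.74 (adjusted p = 0.000566, and adjusted p = 0.617 with an estimated correlation). The collagen gene Col3a1 rose 8.53-fold (3.09 ± 1.32), the proteoglycan Dcn 6.51-fold (2.70 ± 0.96) and the hyaluronan synthase Has2 6.38-fold (2.67 ± 0.85). Lum also rose, but it was above background in the wild-type channel on 1 of the 3 arrays, so no fold is given. Of 15 mesothelial and epithelial markers, 8 fell and none rose (9 and none adjusted over the list alone), with a median of −0.58 (adjusted p = 0.000331, and adjusted p = 0.617 with an estimated correlation). Keratin 19, Krt19, was 17.4-fold lower (−4.12 ± 0.48) and mesothelin, Msln, was 10.6-fold lower (−3.41 ± 0.18). Gpm6a and E-cadherin, Cdh1, were not well above background in the knockout channel and were at least 5.98-fold and 2.90-fold lower there. Of 17 smooth muscle and pericyte markers, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of −0.29 (adjusted p = 0.0056, and adjusted p = 0.617 with an estimated correlation). The call was lost with probes above background in both channels on all arrays (adjusted p = 0.0729). The pericyte proteoglycan Cspg4 (−2.57 ± 0.25) and calponin, Cnn1 (−1.45 ± 0.40), fell. Of 15 macrophage and leukocyte markers 4 fell and none rose, also over the list alone, among them lysozyme 2, Lyz2 (−1.78 ± 0.51), and the list did not pass (adjusted p = 0.153, and 0.0253 without replicate 2). Of 6 adipocyte markers 2 rose and 2 fell, also over the list alone (adjusted p = 0.70 for the list), with Fabp4 10.7-fold and Pparg 4.00-fold lower and the lipase Lpl 6.65-fold higher. Without replicate 1, the log2 ratio of Col3a1 was 3.85, and its call was lost without replicate 2 or 3 (adjusted p = 0.0873 and 0.0933). Calls were also lost for Cnn1 without replicate 2 or 3 (0.0533 and 0.0625), for Cdh1 without replicate 2 (0.06) and, without replicate 3, for Dcn (0.077) and Lum (0.0775). Lpl read 4.33, Has2 3.86, Lyz2 −2.89 and Cnn1 −2.06 with the scanner software's log ratio.

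Matrix genes changed in both directions. Of 64 extracellular matrix genes, 16 rose and 14 fell (22 and 20 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.753). Beside Col6a3, Col11a1 was 17.1-fold lower (−4.10 ± 0.10), whereas Col3a1 and thrombospondin 2, Thbs2 (3.06 ± 0.28), rose. The collagen VI chains Col6a1 (−0.0006 ± 0.44, limma adjusted p = 0.999) and Col6a2 (0.24 ± 0.38, adjusted p = 0.364) did not pass, unlike Col6a3. Fibroblast markers, of which Col3a1 is one, passed as higher in the same comparison (adjusted p = 0.000566, and adjusted p = 0.617 with an estimated correlation). Col3a1 had a log2 ratio of 3.85 without replicate 1 and lost its call without replicate 2 or 3 (adjusted p = 0.0873 and 0.0933). Of 45 matrix proteases and inhibitors, 10 rose and 9 fell (11 and 10 adjusted over the list alone; adjusted p = 0.564 for the list). Transglutaminase 2, Tgm2 (−3.10 ± 0.18), and Adam8 (−1.88 ± 0.22) fell and cathepsin K, Ctsk, rose 6.09-fold. The median and mean of both lists differed in sign (0.000065 and −0.03 for matrix genes, 0.08 and −0.01 for proteases). Col11a1 read −5.48 with the scanner software's log ratio.

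Of 21 genes of MHC class I and II and their peptide transport, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.68 (adjusted p = 0.000061, and adjusted p = 0.682 with an estimated correlation). The class I genes H2-M3 rose 5.72-fold (2.52 ± 0.32), H2-K1 4.25-fold (2.09 ± 0.16) and H2-Q1 3.04-fold, and the transporter Tap2 rose 2.77-fold (1.47 ± 0.65). Probes of related class I genes can share target sequence, so single members of the family are uncertain. Of these genes, 19 lie within 20 Mb of Pim1, and 13 of the 19 (68.4%) were called. Interferon-stimulated genes did not pass as a list, with 3 of 39 higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.931, and 0.0168 without replicate 1), and Irgm1 (−1.17 ± 0.17) and Herc6 (1.08 ± 0.13) moved apart. Of 26 cytokines and chemokines, 7 rose and 4 fell (11 and 5 adjusted over the list alone; adjusted p = 0.108 for the list, 0.0486 without replicate 2 and 0.0422 without replicate 3). The chemokine Cxcl5 rose 9.97-fold (3.32 ± 0.57), the pentraxin Ptx3 3.74-fold and Cxcl16 3.54-fold, and Ccl9 was 3.89-fold lower. Calls were lost for Tap2 without replicate 2 or 3 (adjusted p = 0.101 and 0.126) and for Herc6 without replicate 3 (0.0507). Ptx3 read 3.08 and Herc6 2.07 with the scanner software's log ratio. Fibroblast markers, which passed as higher with the preset correlation (median 0.74, and adjusted p = 0.617 with an estimated correlation), moved the same way as the MHC list.

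Glycolysis and hypoxia, cholesterol synthesis and ribosomal protein genes passed as higher with the preset correlation, although most members of each were not called. Of 37 glycolysis and hypoxia genes, 12 rose and 2 fell (16 and 3 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.00219, and adjusted p = 0.617 with an estimated correlation). The mitophagy receptor Bnip3 rose 3.40-fold (1.77 ± 0.76), the glycolytic regulator Pfkfb3 2.68-fold (1.42 ± 0.18) and the glucose transporter Slc2a1 2.22-fold (1.15 ± 0.17). Of 27 cholesterol synthesis genes, 7 rose and none fell, also over the list alone, with a median of 0.43 (adjusted p = 0.000693, and adjusted p = 0.748 with an estimated correlation). Dhcr7, which forms cholesterol in the last step of synthesis, rose 2.44-fold (1.29 ± 0.42), and Lss, which forms lanosterol, rose 1.77-fold (0.83 ± 0.43). Of 65 cytosolic ribosomal protein genes, 8 rose and none fell (7 and none adjusted over the list alone), led by Rps13 (1.18 ± 0.10), with a median of 0.13 (adjusted p = 0.00402, and adjusted p = 0.752 with an estimated correlation). The ribosomal list missed the threshold with the scanner software's log ratio (adjusted p = 0.177) and without replicate 2 (adjusted p = 0.0676). Of 39 oxidative stress genes, 5 rose and 10 fell (7 and 11 adjusted over the list alone; adjusted p = 0.111 for the list, and 0.0219 without replicate 2), with the glutathione transferases Gsta2 (−2.65 ± 0.18) and Gsta4 (−2.32 ± 0.28) lower beside Gsta1 and metallothionein 2, Mt2, higher (3.04 ± 0.91). Of 38 genes of the unfolded protein and integrated stress response, 6 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.0645 for the list, and 0.0175 without replicate 2), with Trib3 2.68-fold higher. Without replicate 2 or 3, calls were lost for Bnip3 (adjusted p = 0.0786 and 0.116), Dhcr7 (0.0763 and 0.0804) and Lss (0.178 and 0.192), and Mt2 lost its call without replicate 3 (0.0574). Gsta2 read −4.02 with the scanner software's log ratio. The median of fibroblast markers, 0.74, lay in the same direction as those of the 3 lists that passed as higher.

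Of 41 Notch and Wnt genes, 18 fell and 7 rose (22 and 8 adjusted over the list alone), with a median of −0.32 (adjusted p = 0.0109, and adjusted p = 0.682 with an estimated correlation). The call was lost with probes above background in both channels on all arrays (adjusted p = 0.0729). Wnt10a (−3.46 ± 0.15) and the Wnt antagonists Dkk2 (−3.15 ± 0.26) and Sfrp2 fell, while Frzb, another antagonist, rose. Of 41 genes of TGF-beta and BMP signalling, 12 fell and 6 rose (14 and 8 adjusted over the list alone; adjusted p = 0.208 for the list, and 0.0298 without replicate 1). The ligand Tgfb2 (−2.56 ± 0.04), the activin antagonist Fst (−2.22 ± 0.19) and Tgfbi (−2.44 ± 1.00) fell and Eng rose. Of 50 angiogenic factors and receptors, 13 rose and 12 fell (15 and 15 adjusted over the list alone; adjusted p = 0.559 for the list). The guidance ligand Slit3 rose 8.43-fold, and the growth factors Fgf7 6.89-fold, Hgf 6.54-fold and Igf1 4.75-fold. Of 18 mesenchymal transition regulators 3 rose and 2 fell, also over the list alone (adjusted p = 0.87 for the list), among them Twist2 (0.96 ± 0.32) and Sox9 (−0.78 ± 0.22). Of 27 STAT and SOCS genes 2 rose and 1 fell, also over the list alone (adjusted p = 0.138 for the list, and 0.0443 without replicate 1), with the oncostatin M receptor Osmr 2.41-fold higher and Socs1 lower (−0.65 ± 0.16). Without replicate 2 or 3, calls were lost for Twist2 (adjusted p = 0.0976 and 0.11), Sox9 (0.111 and 0.0595), Osmr (0.0868 and 0.0958) and Socs1 (0.13 and 0.14), and Tgfbi lost its call without replicate 3 (0.0636). Dkk2 read −4.12 with the scanner software's log ratio. Mesothelial and epithelial markers (median −0.58) and smooth muscle markers (median −0.29) moved the same way as the Notch and Wnt list, each with adjusted p = 0.617 with an estimated correlation.

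Genes of proliferation and survival, processes in which Pim kinases act, did not pass as lists. Of 50 mitotic genes, 3 rose and 2 fell, and none did when adjusted over the list alone (adjusted p = 0.564 for the list). Of 21 cell cycle inhibitors and D cyclins, 6 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.108 for the list, and 0.0219 without replicate 2). Cyclin D1, Ccnd1 (−1.04 ± 0.29), Rb1 (−1.06 ± 0.33) and Gadd45g (−1.66 ± 0.50) fell, and Cdkn2a rose 1.86-fold. Of 26 genes of the Bcl2 family and apoptosis, 6 fell and 2 rose (8 and 4 adjusted over the list alone; adjusted p = 0.97 for the list). The survival gene Bcl2 (−1.25 ± 0.03) and the death gene Pmaip1 (−1.68 ± 0.15) both fell, and Casp4 rose 4.91-fold. Of 35 Myc and ribosome biogenesis genes 3 rose and none fell, and none passed when adjusted over the list alone (adjusted p = 0.247 for the list, and 0.00738 without replicate 2), with Mycn 2.15-fold higher. Of 15 housekeeping genes 1 was called, also over the list alone, Ywhaz (−0.97 ± 0.27; adjusted p = 0.708 for the list). Without replicate 2 or 3, calls were lost for Ccnd1 (adjusted p = 0.077 and 0.0853), Rb1 (0.0677 and 0.0573), Gadd45g (0.0542 and 0.0636), Cdkn2a (0.145 and 0.17) and Mycn (0.0775 and 0.113). Casp4 lost its call without replicate 3 (0.0754) and Ywhaz without replicate 2 (0.0827). Medians, means or test directions differed in sign for the mitotic, interferon, mesenchymal transition and housekeeping lists, and for the Bcl2 list camera and fry differed in direction.

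**Figure D2:**
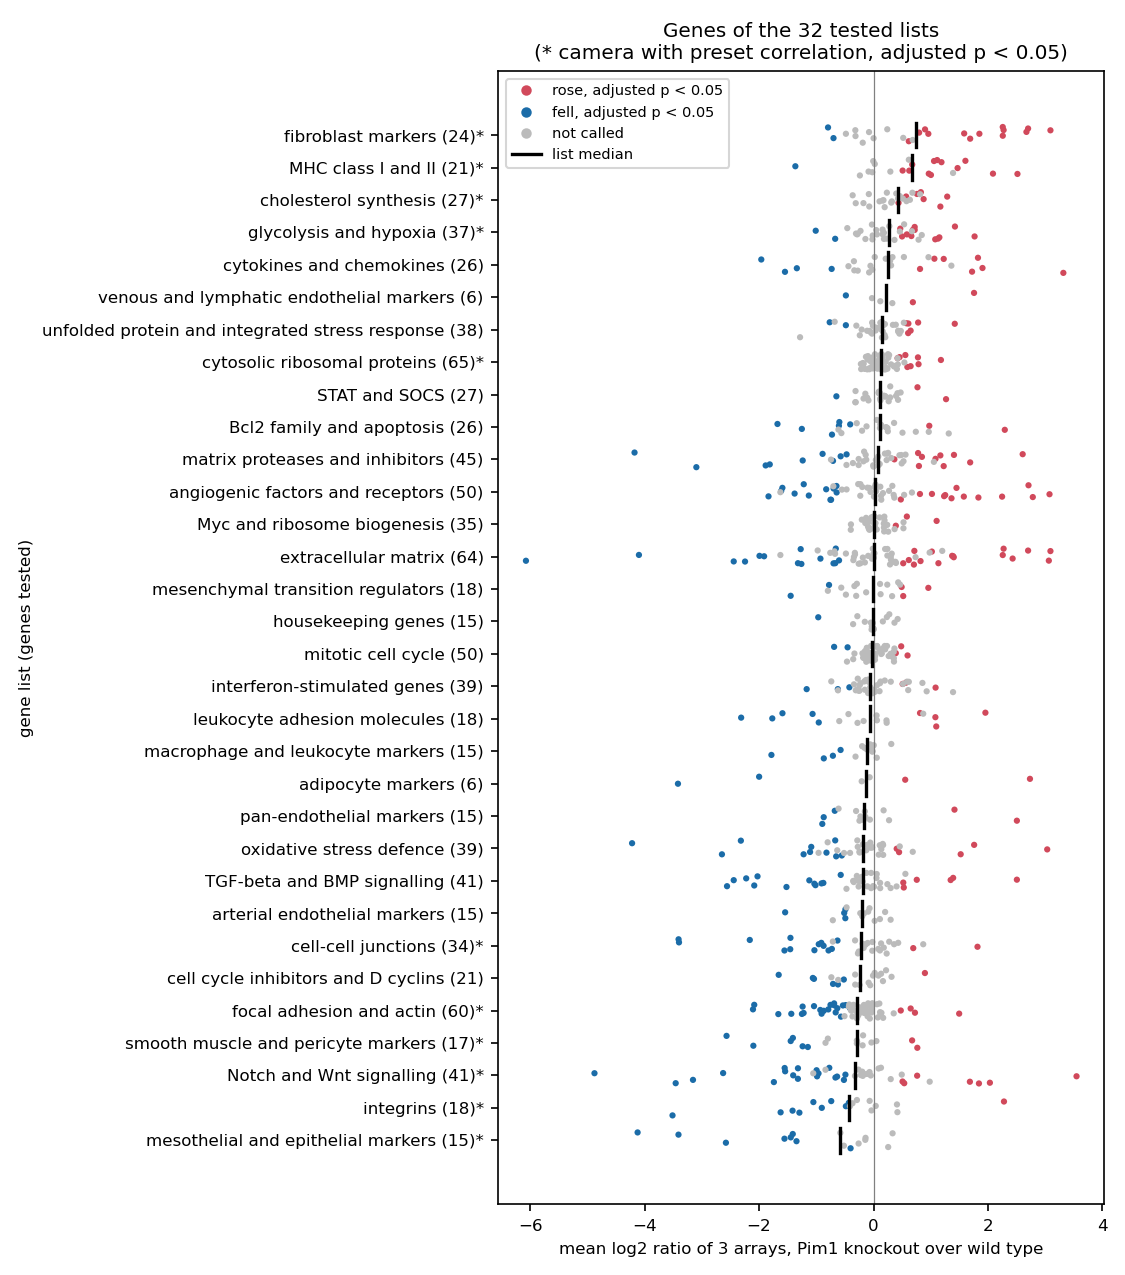
Mean log2 ratio of knockout over wild type over 3 arrays (horizontal axis) for each tested gene (points) of the 32 lists (vertical axis, number of genes in parentheses), coloured by call, with the list median (black bar) and an asterisk for lists that passed camera with the preset correlation. Fibroblast markers had the highest median (0.74) and mesothelial and epithelial markers the lowest (−0.58).

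The neighbourhood of Pim1 was tested because a targeted allele can carry flanking DNA of the strain it was made in. Of 455 genes tested within 20 Mb of Pim1 on chromosome 17, Pim1 itself left out, 84 (18.5%) were called, against 2623 of 13002 (20.2%) elsewhere (odds ratio 0.896, 95% interval 0.696 to 1.14, two-sided Fisher's exact p = 0.405). Of 19 MHC genes in this window, 13 (68.4%) were called, which was counted after seeing the data (odds ratio 8.57 against genes elsewhere, Fisher's exact p = 7.369e-06). The window holds 19 of the 21 MHC genes tested, so this test largely restates the call of that list. It also treats the genes as independent, although their probes can share target sequence, so it decides nothing about flanking DNA. Without them, also a choice made after seeing the data, 71 of 436 were called (odds ratio 0.77, Fisher's exact p = 0.0449). Removing genes known to be mostly called lowers the odds ratio by construction, so no conclusion is drawn from this value.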

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

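The signals in this part come from probes that the comparison of named genes did not use, and the probes named were chosen after their values were seen. Of 2874 tested probes without a gene name, 275 were called, 147 higher and 128 lower in the knockout. Those with the largest log2 ratios were A_52_P615051 (4.80 ± 0.58), on chromosome 7, and A_52_P474528 (4.60 ± 0.46), whose listed position is on chromosome X, among the rises, and A_52_P256421 (−3.31 ± 0.50), on chromosome 1, among the falls. Of 89 tested probes that lie against the strand of their gene, 7 were called, 2 higher and 5 lower. They included 3 assigned to Ramp2, a component of the adrenomedullin receptor (−1.47 ± 0.19, −0.92 ± 0.52 and −0.88 ± 0.53), and 1 in Pim1, at 29218694 to 29218753 on chromosome 17, which was not well above background in the knockout channel and was at least 1.37-fold lower there (adjusted p = 0.0282). The sense probe that represents Ramp2 also fell (−0.68 ± 0.11).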

How the results depend on the processing

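The alternatives without chromosomes X and Y and without MHC genes were chosen after the results were seen; the other settings were planned. Over the counts, the Pim1 value, the Pim1 window and the 32 lists, 391 of 469 alternative values were classed as unchanged. A count was so classed if it lay within 1.5 times of the main count. Any other value was so classed if it kept its side of the threshold and, where called, its direction. Uncalled values could change direction and still be classed as unchanged. Pim1 kept its direction and its call in 19 of 19 (log2 ratio −1.55 to −0.98, adjusted p 1.303e-08 to 0.0476). Of 2682 alternative values for other named genes, 244 lost the call and none changed direction. These values are not all distinct checks. The scanner software's log ratio and the deposited value table were identical but counted separately, also for Pim1 and the counts. Stricter tests and the trend with robust variances reuse the same ratios, so direction could not change there. Leaving out a replicate could not turn genes with the same sign on all arrays, as 2710 of the 2714 called genes had. No called list changed the sign of its median, whereas medians of some lists that did not pass did, and median centring moved the median of all genes to 0.0821. Signal over background limits dim genes, for which only bounds can be given. The cause of the changes that follow was not tested, except that a stricter threshold lowers the number of calls by construction. Fewer arrays did not always lower it: 5582 genes were called without replicate 1, against 2714 with all arrays. Each array holds both genotypes, so the test of its ratio against 0 is itself the paired comparison.

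Of 4300 probes and 2714 genes called, array weights gave 7046 and 4330, an adjusted p under 0.01 gave 1375 and 960, a test against a log2 ratio of 0.5 gave 914 and 671, and median centring gave 2724 probes. The scanner software's log ratio and the deposited value table each gave 1701 genes changed at least 2-fold. Without 1 replicate, called probes ranged from 843 to 9096, called genes from 616 to 5582 and 2-fold genes from 612 to 1005. The Pim1 window without MHC genes had an odds ratio of 0.77 (Fisher's exact p = 0.0449), a fall fixed by removing genes that were mostly called.

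For lists, values are adjusted p. The scanner software's log ratio gave 0.177 for ribosomal proteins. Median centring gave 0.0475 for arterial markers, 0.02001 for macrophage markers and 0.02001 for the unfolded protein response. Without a filter on dim probes, cell cycle inhibitors and the unfolded protein response each had 0.0422. With probes above background in both channels, integrins, smooth muscle markers and Notch and Wnt genes each had 0.0729, and venous and lymphatic markers had 0.04996. The mean of a gene's probes gave 0.0335 for the unfolded protein response.

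With an estimated correlation in camera the value was 0.617 for integrins, junctions, focal adhesion, smooth muscle, fibroblast and mesothelial markers and glycolysis, 0.682 for MHC and for Notch and Wnt genes, 0.748 for cholesterol synthesis and 0.752 for ribosomal proteins. Directional fry turned the direction of the matrix proteases, which were lower (0.0269), and gave 0.0269 for venous and lymphatic markers and for TGF-beta and BMP signalling. It gave 0.062 for fibroblast markers, 0.0694 for MHC and for Notch and Wnt genes, 0.106 for glycolysis, 0.188 for cholesterol synthesis and 0.224 for ribosomal proteins, which miss the threshold. Fry sets a list against no change and not against other genes, so it answers another question than camera. These lists also missed camera with an estimated correlation. So did the other called lists (integrins, junctions, focal adhesion, smooth muscle and mesothelial markers). Whether the calls of any of the 11 lists with the preset correlation hold is therefore not settled. The mixed form of fry passed for 31 of 32 lists, which says only that members changed in either direction. Among the lists that camera did not call, its value was 0.00026 for extracellular matrix and for angiogenic factors, 0.00104 for proteases and for cytokines, 0.00135 for leukocyte adhesion, venous and lymphatic markers, interferon-stimulated genes and TGF-beta and BMP signalling, 0.00316 for general endothelial markers and for STAT and SOCS, 0.00608 for arterial, 0.0377 for macrophage and 0.00175 for adipocyte markers, 0.0125 for mitotic genes, 0.00437 for cell cycle inhibitors, 0.00147 for the Bcl2 family, 0.00251 for mesenchymal transition, 0.000801 for the unfolded protein response, 0.000588 for oxidative stress and 0.0099 for housekeeping genes.

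Without 1 replicate, the value ranged from 0.0168 to 0.815 for interferon-stimulated genes, from 0.0298 to 0.226 for TGF-beta and BMP signalling, from 0.0443 to 0.323 for STAT and SOCS, from 0.0253 to 0.336 for macrophage markers, from 0.0219 to 0.504 for cell cycle inhibitors and for oxidative stress, from 0.0422 to 0.0982 for cytokines, from 0.00738 to 0.309 for Myc and ribosome biogenesis, from 0.0175 to 0.363 for the unfolded protein response and from 0.00415 to 0.0676 for ribosomal proteins.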

Other observations

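Among the tests in this part, those of exchanged dye labels, of the 2 shifts in cell composition and of MHC genes near Pim1, and the counts by chromosome, were chosen after the results were seen. The 2-fold changes were spread over the genome: the share of tested genes ranged from 4.79% on chromosome 11 to 10.1% on chromosome 6 among the autosomes, and 33 of 442 tested genes on chromosome X were among them. Genes of the sex chromosomes made up 4.00% of the 901 genes, against 3.32% of the genes tested, so they account for few of the calls. Among the 12 largest falls, however, Xist, Fhl1, Xlr4b and Chst7 lie on chromosome X.

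The first pattern is the difference in sex-linked genes. Cells of opposite sex in the 2 channels, male in the knockout, are a candidate explanation: before their values were looked at, it was set to need a median under −0.3 for the X-linked genes that escape inactivation, and Kdm6a, Kdm5c, Eif2s3x and Ddx3x had −0.66, although Ddx3x (adjusted p = 0.0934) and Kdm5c (adjusted p = 0.0977) did not pass singly. It also needed Kdm5d and Uty to be higher in the knockout, and both were on 3 of 3 arrays, although Uty did not pass the threshold (adjusted p = 0.0719); a first reading that asked Uty to pass, which the prediction had not, was dropped after its value was seen. Exchanged dye labels stay open, since Pim1 was lower in the channel labelled knockout (log2 ratio −1.04, SE 0.10) but its probe decides nothing while the deleted part is unknown, and an exchange would still leave the channels of different sex. Whether the animals, the cultures or the labels differ was not tested, and an effect of sex or of the individual cultures on other genes cannot be separated from the genotype here.

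The second pattern is the 901 genes changed at least 2-fold, for which technical sources tied to single probes were tested. A dye bias of single sequences should not carry over to a second probe, yet the second probe had the same sign in 97.9% of 381 genes. Base composition accounted for 0.218% of the variance of the log2 ratio over all tested probes. The base composition argues against that source as the main one. The second probes argue against dye bias only where the sequences do not overlap. Overlap was not checked, since any differing sequence counted. Of the 901 genes 520 had no second probe, and a dye effect common to a whole transcript stays open without a swap. With 3 arrays only 4 sign patterns exist, so no share under 0.05 can be reached: the real orientation gave 4300 probes, 2714 genes and 901 genes at 2-fold, in each case 1 of the 4 patterns with as many, and the others gave at most 0.

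The third pattern is the shift in markers of other cell types. Of 15 mesothelial and epithelial markers 86.7% had ratios under 0 and none of the 8 called rose, which would be consistent with a larger share of such cells in the wild-type cultures and equally with lower expression in the same cells; of the 18 listed, 3 also stand in another list, as do 10 of the 26 for fibroblasts, and Krt19 and Msln stayed above background in the knockout. Of the 18, 10 were above background on all arrays in the knockout channel and 12 in the wild-type channel. Wt1 went the other way (3 knockout arrays and 1 wild-type array), as did Rspo1 (3 and 2). Of 23 called fibroblast and smooth muscle markers 65.2% rose and 8 fell. Those 2 lists were known to move apart before they were pooled, so this count decides nothing. Fibroblast markers alone, with 13 rising and 2 falling, leave a larger share of fibroblasts open, although Col6a3 fell by 6.07 on the log2 scale. Col6a3 is a single gene outside that list, and Col6a1 and Col6a2 did not pass. General endothelial markers such as Pecam1 and Cdh5 were at background in both channels. Some others were not: of 36, 11 were above background on all arrays in the knockout channel and 14 in the wild-type channel. On no array in either channel were 14 of the 36 above it. Tek, Emcn, Vwf, Robo4, Cldn5 and Icam2 were above it on 1 wild-type array only. The make-up of these cultures is a hypothesis to test in cells, not a finding.

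Other values were as follows. Within 20 Mb of Pim1 the odds ratio of calls was 0.896 (upper 95% bound 1.14), so no excess over all genes of the window was seen, whereas 68.4% of its 19 MHC genes were called, for which flanking DNA of another strain stays open. The median SD between arrays was 0.156 in the wild-type channel and 0.136 in the knockout channel, a ratio of 1.14; since each genotype always carried the same dye, this does not decide whether 1 wild-type RNA was used on all arrays. The bound set beforehand against a single RNA (a ratio of 0.9 or more) was met, but it had overlooked that dye noise and RNA spread cannot be separated in this design, which was recognised after the value was seen.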
